A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

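FAIRE and input DNA from giant colonies of strain BY4742 were sequenced at biomasses of 4 mg and, in steps of equal ratio, 20 mg, 100 mg and then 500 mg, with 3 biological replicates each, 24 samples in all. Per the labels, FAIRE samples were fixed with formaldehyde and input samples were not, DNA was sheared by sonication and purified with phenol-chloroform, and libraries were made with ThruPLEX reagents from a few nanograms of DNA and sequenced with single-end reads on a NextSeq 500. Bowtie2 2.2.8, SAMtools 1.4, bedtools 2.26.0, FastQC 0.11.5 and MACS2 2.1.1.20160309 were named, with build R64 (sacCer3), per the submitters' processing notes. Their settings, the peak threshold and the treatment of reads with several map positions are not given in the sources used here. Per the labels, 1 peak list was made from each pair of a FAIRE and an input library, so replicates were not pooled. The 12 input libraries were used only through these lists.

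Each deposited list gave, per peak, start and end positions and the summit position, in bp and counted from 0, which were turned into 1-based coordinates. The deposited score of a peak was 10 times its −log10 q, rounded down, and was not used beyond that check. The deposited fold enrichment, a ratio of FAIRE over input signal at the summit, was made by the authors' peak caller, as were the deposited −log10 p-value and −log10 q-value columns. The lowest −log10 q per list was between 1.00 and 1.52. Fold enrichment depends on the depth and enrichment of each library, so it was never compared between lists. It was summarised as the median of 12 lists, or for separating promoters as the mean of the 3 lists in which they were marked. The 3000 or 500 strongest and the 500 weakest peaks of a list were chosen by the deposited −log10 p-value and not by fold enrichment. Read totals were not analysed here. The input level and the FAIRE pileup were recovered per peak by solving the fold enrichment and the −log10 p for the 2 values under a Poisson model. The recovered FAIRE pileup was whole within 0.02 for 100% of peaks in 9 libraries and for 4.00% in 4 mg replicate 2, 3.73% in 4 mg replicate 3 and 3.73% in 100 mg replicate 1. A low recovered input level of each list, the percentile 1 over its peaks, was divided by its shortest peak, which MACS2 sets to its fragment length by default. The quotient was taken as reads per bp, an indirect measure of the depth after scaling of a FAIRE and input pair by the caller. It lay between 0.24985 and 0.25004 in those 9 libraries and between 0.236 and 0.239 in the other 3. Any scaling or equalising of read numbers is not given in the sources used here.

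Gene positions came from a RefSeq table of assembly R64, the same build, and strands from the systematic names. Its models hold no untranslated regions. Of 6002 protein-coding nuclear genes with a strand, 6000 had a full window of 500 bp upstream of the start codon, within the chromosome. A promoter was marked when at least 1 distinct summit lay in the window. Summits in the window, total peak length, the percent of promoters marked and the Jaccard index of peak length were computed per list. Recovery was the percent of regions shared by 2 of the 500 mg libraries (50 bp or more) that a list covered by at least 50 bp. For the lower biomasses it was averaged over the 3 pairs of 500 mg libraries, and for a 500 mg library it used the pair that left it out. These regions were not remade in the permutations, so the p-values for recovery favour 500 mg by construction.

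The 4 biomasses were compared by exact permutation tests over all 369600 assignments of 12 lists to 4 groups of 3, on the percent of variance between groups. Follow-up tests were exact and two-sided, over 220 splits for 3 lists against 9 and 20 for 3 against 3, whose smallest p is 0.1. Similarity within biomasses was tested one-sided over all partitions of the lists into 4 groups of 3. The 6 tests over the 4 biomasses formed 1 family for Benjamini-Hochberg adjustment. Promoters marked in 3 of 3 lists of a lower biomass and 0 of 3 at 500 mg, or the reverse, were counted and set beside the 10 splits of the 6 lists. For 29 gene lists, members marked in all 12 libraries were compared with other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. Genes with a shared divergent window are not independent in this test. The lists are not independent of each other either, since 48 genes were held by more than 1 list. Tests, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to come after. The contrast of 20 mg minus the other 9 libraries was chosen after seeing the data.

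Genes were named by 4 rules: in each list the 3 members marked in all libraries with the highest median fold enrichment and the 2 marked in the fewest, the 10 strongest promoters marked in all libraries, the 5 separating promoters with the highest mean fold enrichment per direction, and a fixed set of deletion markers, ATO, mating type and reference genes. The text leaves out some members of groups it does not describe.

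The alternatives were a −log10 q of 5 or more, the 3000 strongest peaks of each list, removal of mitochondrial and ribosomal DNA peaks, windows of 250 and 1000 bp, marking by an overlap of 50 bp, marking in at least 9 of 12 libraries, 1 gene per shared window, the share of the shorter list's peaks in place of the Jaccard index, a replicate block, and leaving out each FAIRE library. Chosen after seeing the data were the 500 strongest peaks, lists without peaks of 3 kb or wider, and tests without the 20 mg or the 500 mg libraries. Repeat regions were 35 long Ty reading frames and 8 YRF1 genes of the Y' elements. Positions shifted at random along chromosomes, 100 draws, gave the chance overlap of tRNA and snoRNA genes and of weak coding peaks.

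Procedures were tested on simulated data. With no effect, the exact test passed 0.05 in 3% of 200 simulations of the 4 biomasses, and with 20 mg shifted by 4 SD it passed in 96% of 100. With the replicate block and no effect 7% of 100 passed. For 4 mg against 500 mg, 200 of 200 seeded promoters among 6000 genes were found, which the seeding fixed in advance and which says nothing about sensitivity. There were 15 unseeded ones, with marks drawn independently for each library, unlike the real lists. In the list test the seeded list was found and 0 of 28 others passed. Recovered input levels lay within 1% of the simulated ones in 100% of 488 values. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.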

Results

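FAIRE recovers DNA that is poorly bound by protein: chromatin is fixed with formaldehyde and sheared, and the fragments left in the aqueous phase of a phenol-chloroform extraction are sequenced. Here it was applied to giant colonies of the yeast strain BY4742, a laboratory strain of mating type alpha with deletions of auxotrophic marker genes, which had grown for 3 days on a glycerol and ethanol medium with a pH dye. The question named in the series title is how the assay can be adapted to low cell numbers. Material was taken at 4 biomasses that rose in steps of equal ratio from 4 mg through 20 mg and 100 mg to 500 mg, with 3 biological replicates of each, and every FAIRE library had its own input library of unfixed DNA. The 24 samples gave 12 peak lists, each of a FAIRE library against its own input. The lists held between 4180 and 6439 peaks, on average 5323 ± 698 (SD, n = 12 libraries). The median peak width per list was 304.5 ± 21.6 bp (SD, n = 12). Read totals were not analysed here. The depth recovered indirectly from the deposited fold enrichments and p-values was 0.250 reads per bp in 9 libraries, and 0.239 in 4 mg replicate 2, 0.238 in 4 mg replicate 3 and 0.236 in 100 mg replicate 1. The fold enrichments quoted are the authors' own, as a median over the 12 lists. Promoters separating a biomass from 500 mg were ranked by the mean over the 3 lists in which they were marked. The strongest and weakest peaks of a list are those with the highest and lowest deposited −log10 p, whereas promoters are ranked by fold enrichment. Coordinates are 1-based on build R64 (sacCer3).

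In each of the 12 libraries the strongest peaks lay upstream of genes more often than the weakest peaks, although coding sequence held many of both. Among the 500 strongest peaks of a list, 41.7% ± 7.44 (SD, n = 12) of summits lay in noncoding sequence within 500 bp upstream of a start codon, which is 16.0% of the genome, and 43.5% ± 9.70 lay in coding sequence. Among the 500 weakest, 6.38% ± 2.18 lay in that upstream noncoding sequence and 85.3% ± 4.92 in coding sequence, which makes up 72.8% of the genome. The share of all summits in coding sequence was between 74.7% and 80.9% per library. Upstream noncoding sequence held 14.5% ± 1.44 of all summits (SD, n = 12), between 12.9% and 17.5% per library, near its 16.0% of the genome. Summits were most frequent 300 to 400 bp upstream of start codons, with 436.5 ± 38.7 per library in that 100 bp interval, and 100 to 200 bp inside the gene, with 525.6 ± 57.7. Between them, in the 100 bp just upstream of the start codon, there were 56.8 ± 15.6 (all SD, n = 12). For the 500 strongest peaks the corresponding values were 99.2 ± 17.8, 42.6 ± 10.4 and 7.17 ± 2.59. Gene models carried no untranslated regions, so distances refer to the start codon and not to the transcription start.

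**Figure D1:**
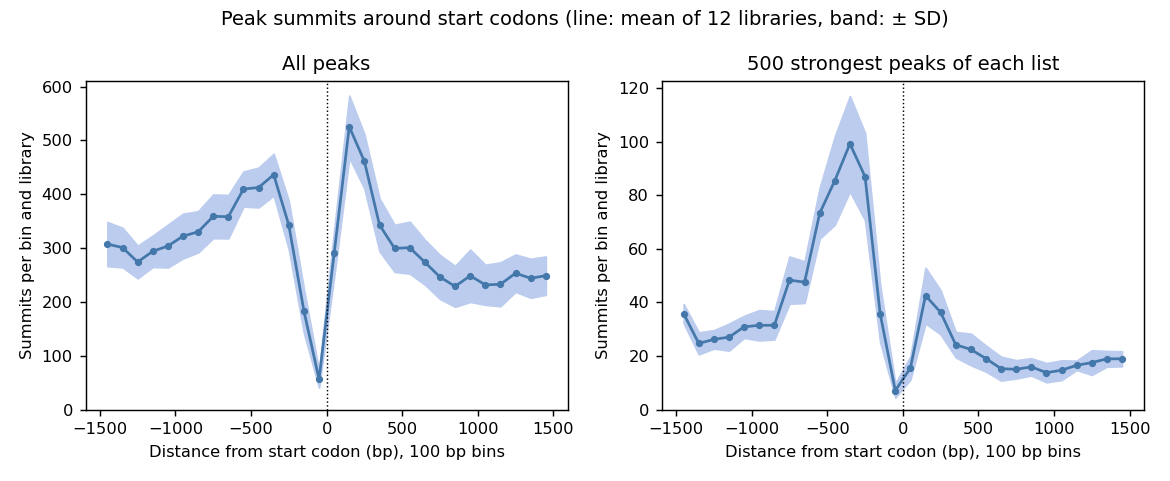
Number of peak summits per library in 100 bp intervals of distance from the start codon (horizontal axis, bp, negative upstream), for all peaks and for the 500 strongest of each list. Lines are means of 12 libraries and bands ± SD. All peaks form maxima on both sides of the start codon with a minimum of 56.8 just upstream of it, and the strongest peaks form 1 main maximum, 99.2, upstream.

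Which promoters were marked whatever the biomass was asked first. A promoter was counted as marked in a library when at least 1 summit lay in the 500 bp upstream of the start codon. Of 6000 nuclear protein-coding genes, 584 (9.73%) were marked in all 12 libraries, 3481 (58.0%) in none. The strongest of the 584 lay upstream of LYS21, which encodes homocitrate synthase of lysine synthesis (chromosome IV, window 226893 to 227392), with a median fold enrichment of 3.88 over the 12 lists. It was followed by the divergent pair HNT1 and YDL124W (3.74), PYC2, a pyruvate carboxylase gene (3.68; chromosome II, 662250 to 662749), and CTT1, encoding cytosolic catalase (3.65; chromosome VII, 654134 to 654633). SPI1, encoding a cell wall protein, also had 3.65, CCC2, encoding a copper transporter, and PRM4 had 3.60, and GPP2, encoding a glycerol phosphate phosphatase, had 3.60. YJL107C, the last of the 10, had 3.57. Of the genes deleted in BY4742, LEU2, URA3 and LYS2 had neither a marked promoter nor a peak over the coding sequence in any library. HIS3, which carries a partial deletion in this strain, had a marked promoter in 1 library and a peak over its coding sequence in 12. MATALPHA1 and STE3 had no marked promoter in any library and STE2 had 1, while ACT1, the actin gene, had none although a peak lay over its coding sequence in all 12 libraries.

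Ribosomal protein, histone and ATO genes were over-represented among the 584. Of 137 ribosomal protein genes, 58 (42.3%) were marked in all 12 libraries against 8.97% of the other genes (Fisher's exact test, two-sided, adjusted p = 7.35e-23), while 51 were never marked. RPS0A had the highest median fold enrichment of the group, 3.45 (chromosome VII, 920075 to 920574), then RPL31A and RPL6A with 3.43 each, whereas RPL10 and RPL11B were never marked. Histone genes followed, with 8 of 10 marked in all 12 libraries (80% against 9.62%, Fisher's exact test, adjusted p = 4.21e-06), led by HTZ1, encoding the H2A variant H2A.Z (3.34), HTB1 (3.10) and HTA2 (3.03). HTA1 was marked in 7 libraries and HHO1, the linker histone gene, in 1. All 3 ATO genes, which encode plasma membrane proteins associated with ammonium export in yeast colonies, were marked in all 12 libraries (Fisher's exact test, adjusted p = 0.00887): ADY2, also called ATO1, had a median fold enrichment of 3.37, ATO2 3.26 and ATO3 2.82.

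The lists for the TCA cycle, for gluconeogenesis and for trehalose and glycogen went in the same direction. TCA cycle genes were marked in all 12 libraries in 6 of 17 cases (35.3% against 9.66%, Fisher's exact test, adjusted p = 0.0194), with KGD1, of 2-oxoglutarate dehydrogenase, at 3.16, IDH1, of isocitrate dehydrogenase, at 2.98 and FUM1, fumarase, at 2.90. CIT3 was never marked. The list for gluconeogenesis, the glyoxylate cycle and use of 2- or 3-carbon compounds had 7 of 21 genes marked throughout (33.3% against 9.65%, Fisher's exact test, adjusted p = 0.0194). It was led by ADY2 (3.37), which the ATO list holds too, MLS1, malate synthase (3.26), and IDP2, cytosolic isocitrate dehydrogenase (3.24). ADR1, encoding a transcription activator of this pathway, and PCK1, the phosphoenolpyruvate carboxykinase gene, were never marked, although a peak overlapped the PCK1 window in every library. Trehalose and glycogen genes had 6 of 17 (35.3% against 9.66%, Fisher's exact test, adjusted p = 0.0194), with PGM2, phosphoglucomutase (3.16), TPS3, of trehalose synthesis (3.10), and GSY2, glycogen synthase (3.04). Of the glycolysis and fermentation genes, ADH1 and CDC19 were marked in no library, although a peak overlapped the CDC19 window in every library. The list had 4 of 21 marked throughout (Fisher's exact test, adjusted p = 0.277), TDH2, PGK1 and HXK2 among them. This call depended on the rule for marking: the list passed by overlap (12 of 21, adjusted p = 0.00559), in windows of 1000 bp (13 of 21, 0.00286) and when 9 of 12 libraries sufficed (9 of 21, 0.0234), in Fisher's exact test, with a range of 0.00286 to 1 over all 20 alternatives. Respiratory chain genes had 3 of 23 (Fisher's exact test, adjusted p = 0.640), ATP synthase genes 2 of 14 (0.773) and genes of peroxisomal beta-oxidation 1 of 13 (adjusted p = 1).

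Subtelomeric genes, within 20 kb of a chromosome end, were marked throughout less often than other genes, with 11 of 235 (4.68% against 9.94%, Fisher's exact test, adjusted p = 0.0274). In the mean per biomass they were not marked less often, with 24.3%, 27.9%, 25.8% and 24.3% of members in order of rising biomass. For all genes tested these values were 22.8%, 26.0%, 24.4% and 21.8%. The lower share thus concerns marking in every library, and was 17.4% against 18.1% when 9 of 12 libraries sufficed. CHA1, the serine and threonine deaminase gene, shared its marked window with VAC17 (3.12). Leaving out 4 mg replicate 3 gave an adjusted p of 0.0914 for this list, leaving out 20 mg replicate 2 gave 0.164 and leaving out 100 mg replicate 2 gave 0.0545, with a range of 0.000236 to 1 over all 20 alternatives. In all, 6 of 29 lists had members marked more often and 1 less often after Benjamini-Hochberg adjustment over the 29 lists, and 10 passed an unadjusted p of 0.05. When windows shared by neighbouring genes were counted once, which left 4597 genes, 3 lists passed: ribosomal proteins with 41 of 103, histones with 5 of 6 and the ATO genes with 3 of 3. With a promoter window of 250 bp only the ribosomal proteins passed (33 of 137, Fisher's exact test, adjusted p = 4.8e-26), and none of the TCA cycle genes, none of the gluconeogenesis genes and none of the histone genes was marked in all libraries. Among the 3000 strongest peaks the calls for the ATO genes (1 of 3, Fisher's exact test, adjusted p = 0.306), TCA cycle (2 of 17, 0.421), gluconeogenesis (4 of 21, 0.111) and trehalose and glycogen genes (4 of 17, 0.0738) were lost. The trehalose and glycogen list also missed the threshold at a −log10 q of 5 or more, in windows of 1000 bp and by overlap (Fisher's exact test, adjusted p = 0.0519, 0.0533 and 0.0869), the ATO genes did so in the first 2 of these (0.0823 and 0.0503), and the subtelomeric list did so when 9 of 12 libraries sufficed (0.927).

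**Figure D2:**
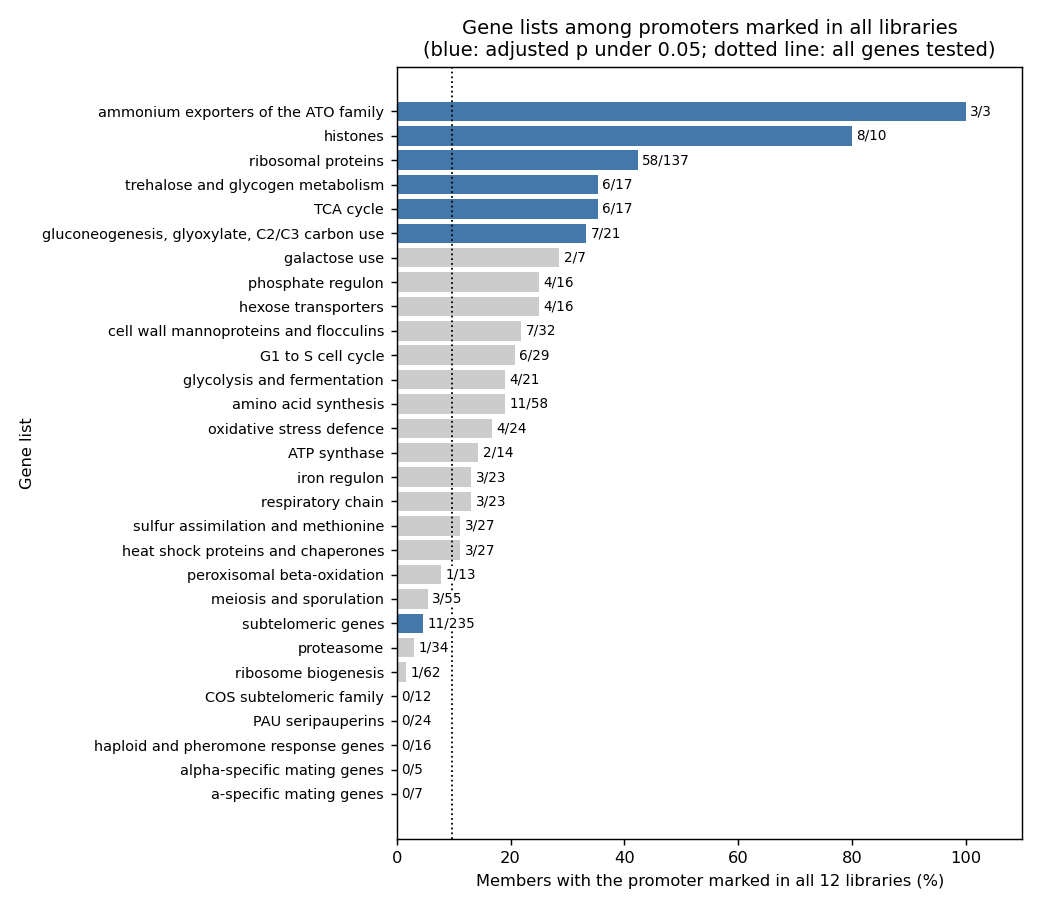
Percent of the members of each of 29 gene lists whose promoter was marked in all 12 libraries (horizontal axis), with the counts beside the bars. Blue bars passed Benjamini-Hochberg adjusted p of 0.05 in Fisher's exact test, and the dotted line is the share of all genes tested, 9.73%. The ATO genes, histones and ribosomal proteins lie highest at 3 of 3, 8 of 10 and 58 of 137.

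Samples of 20 mg gave the most peaks. There were 6292 ± 128 peaks at 20 mg, 4896 ± 283 at 4 mg, 5008 ± 812 at 100 mg and 5096 ± 126 at 500 mg (SD, n = 3 each). The lowest 20 mg library, with 6204 peaks, lay above the highest library of any other biomass, 100 mg replicate 3 with 5804. The wide spread at 100 mg came from libraries of 4180, 5039 and 5804 peaks. Of the variance between libraries, 71.2% lay between the biomass groups (exact permutation test over 369600 assignments, two-sided by construction, p = 0.0214, adjusted p = 0.0427 over 6 tests). Anything else shared by the libraries of a biomass cannot be told apart from biomass in this test. The 20 mg libraries exceeded the other 9 by 1292 peaks (two-sided exact permutation test, p = 0.00455). This contrast was chosen after seeing the data, so its p restates that they lay above the others and adds no support. The 4 mg libraries differed from the other 9 by -569 peaks (exact p = 0.259), and by -156 (exact p = 0.655) without the 20 mg libraries, also chosen after seeing the data. Against 500 mg the differences were -200.0 at 4 mg (exact p = 0.4), 1196 at 20 mg (exact p = 0.1) and -88.0 at 100 mg (exact p = 0.8), where 0.1 is the smallest two-sided p that 3 libraries against 3 can give. At a −log10 q of 5 or more they were -599, 648 and -1141, each with an exact p of 0.1. Leaving out 20 mg replicate 2 gave p = 0.0541 for the 4 biomasses in the exact test, and leaving out 100 mg replicate 1 turned the difference between 100 mg and 500 mg to 325.8 peaks. That difference was -486 without 100 mg replicate 3, -139 without 500 mg replicate 1 and -17.8 without 500 mg replicate 3, and the difference between 4 mg and 500 mg was -313 without 4 mg replicate 1, -41.2 without 4 mg replicate 2 and -130 without 500 mg replicate 3.

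The length of genome covered by peaks was 2273 ± 285 kb at 4 mg, 2694 ± 243 kb at 20 mg, 2113 ± 321 kb at 100 mg and 2590 ± 72.1 kb at 500 mg (SD, n = 3 each). The exact permutation test over the 4 biomasses gave 57.0% of the variance and p = 0.0647 (adjusted p = 0.0777). Without 4 mg replicate 2 the exact p was 0.0252, and without 20 mg replicate 3 the mean at 20 mg minus that at 500 mg turned from 104.1 kb to -32.9 kb.

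Over whole lists, promoter regions took a larger share of the summits at 4 mg and 100 mg than at 20 mg and 500 mg, an order that did not hold among the 500 strongest peaks. The share of summits within 500 bp upstream of a start codon was 23.9% ± 0.755 at 4 mg, 21.4% ± 0.466 at 20 mg, 24.8% ± 0.645 at 100 mg and 21.97% ± 0.168 at 500 mg (SD, n = 3 each). These windows make up 21.3% of the genome. Of the variance between libraries, 90.3% lay between the biomass groups (exact permutation test, p = 0.000779, adjusted p = 0.00468 over 6 tests). All 3 libraries at 4 mg and all 3 at 100 mg lay above all 3 at 500 mg, by 1.93 and 2.83 percentage points in the mean, and the 20 mg mean differed from that at 500 mg by -0.569 points, each with an exact p of 0.1. Without 20 mg replicate 3 the last of these was -0.303. Among the 3000 strongest peaks of each list the shares were 29.2% ± 0.214, 27.6% ± 0.404, 30.8% ± 5.16 and 27.2% ± 0.208 in order of rising biomass, and the exact test gave p = 0.352. There 4 mg exceeded 500 mg by 1.94 points and 100 mg by 3.53, with the larger spread at 100 mg. Among the 500 strongest, an alternative chosen after seeing the data, 4 mg minus 500 mg was -9.13 points (exact p = 0.2) and 100 mg minus 500 mg -10.0 (exact p = 0.3).

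Of the 6000 genes, 22.8% ± 0.561 had a marked promoter at 4 mg, 26.0% ± 1.04 at 20 mg, 24.4% ± 4.58 at 100 mg and 21.8% ± 0.494 at 500 mg (SD, n = 3 each). The 100 mg libraries covered the whole range, from 20.2% in replicate 1 to 29.3% in replicate 3. In that replicate 3, 64.5% of peaks had a −log10 q of 5 or more, the lowest such percent of all libraries. The difference between biomasses did not pass the exact permutation test (40.5% of the variance, p = 0.210, adjusted p = 0.210). Without 100 mg replicate 1 the exact p was 0.0458, and without 100 mg replicate 3 it was 0.0142.

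Ribosomal protein promoters were marked in 52.8% ± 0.421 of members at 4 mg, 55.0% ± 1.11 at 20 mg, 52.1% ± 5.57 at 100 mg and 50.6% ± 0.421 at 500 mg (SD, n = 3 each; exact permutation p = 0.384). Of the 29 lists, 0 differed between biomasses after Benjamini-Hochberg adjustment of the exact permutation tests and 2 had an unadjusted p under 0.05. Oxidative stress genes were marked in 41.7%, 37.5%, 44.4% and 33.3% of members in order of rising biomass (exact p = 0.0335), and meiosis and sporulation genes in 8.48%, 17.0%, 10.9% and 9.70% (exact p = 0.0481).

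**Figure D3:**
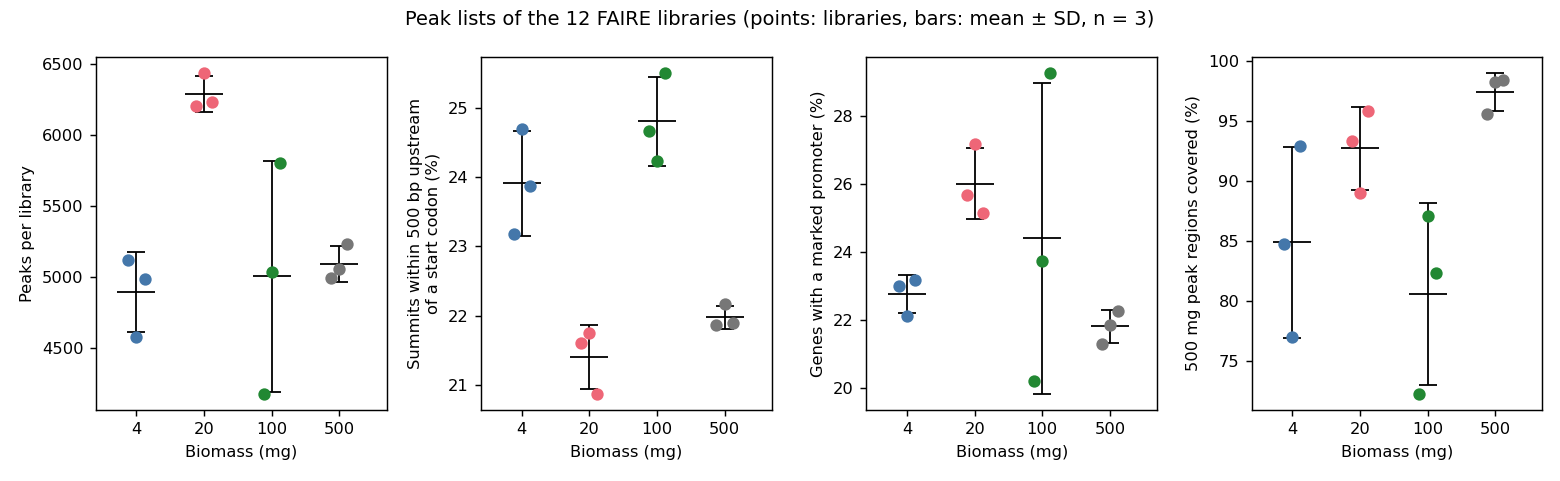
Number of peaks, percent of summits within 500 bp upstream of a start codon, percent of genes with a marked promoter and percent of 500 mg peak regions covered, plotted against biomass in mg. Points are libraries and bars mean ± SD (n = 3). The 3 libraries at 20 mg, from 6204 to 6439 peaks, lie above the other 9, and the vertical axes do not start at 0.

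Most regions found at 500 mg were found again at the lower biomasses. Chance coverage of these regions was not computed. For the 500 weakest coding peaks of the 500 mg libraries, shifted positions were covered for 18.5% to 31.2%, most often by 20 mg replicate 3. Regions shared by a pair of 500 mg libraries, numbering 4903, 4996 and 5079, were covered for 84.9% ± 7.97 by the 4 mg libraries, 92.7% ± 3.47 by the 20 mg libraries and 80.6% ± 7.57 by the 100 mg libraries (SD, n = 3 each). A left-out 500 mg library covered 97.4% ± 1.58. The lowest library was 100 mg replicate 1 with 72.3%, and the highest below 500 mg was 20 mg replicate 3 with 95.8%. Against 500 mg the differences were -12.5 percentage points at 4 mg, -4.72 at 20 mg and -16.9 at 100 mg, with exact p of 0.1, 0.2 and 0.1. Among the 3000 strongest peaks of each list they were -8.57, -16.1 and -15.4, so that the 20 mg mean went from the highest of the lower biomasses to the lowest. At a −log10 q of 5 or more they were -7.23 at 20 mg and -27.7 at 100 mg, and without 20 mg replicate 2 the difference at 20 mg was -2.85. Over the 4 biomasses the exact permutation test gave 65.7% of the variance and p = 0.0373, with an adjusted p of 0.0560. The regions came from the 500 mg libraries and were kept in every assignment. The 500 mg libraries are therefore favoured by construction, and the p-values for recovery do not measure biomass alone. The unadjusted exact p rose to 0.0578 without 4 mg replicate 1, 0.0639 without 20 mg replicate 1, 0.0616 without 20 mg replicate 3, 0.0571 without 100 mg replicate 1 and 0.0659 without 100 mg replicate 3.

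On average, pairs of lists of the same biomass overlapped more than pairs of different biomasses, but this did not hold within each biomass. The Jaccard index, the shared peak length divided by the combined peak length, averaged 0.703 within biomasses and 0.630 between them, a difference of 0.0730 (one-sided exact permutation test over all partitions into 4 groups of 3, p = 0.00526, adjusted p = 0.0158 over 6 tests). The 500 mg libraries had the highest values, 0.889 on average with a range of 0.881 to 0.899. The 4 mg and 20 mg libraries averaged 0.677 and 0.685 among themselves and the 100 mg libraries 0.560. Pairs of a 4 mg and a 500 mg library averaged 0.737, above the pairs within 4 mg, while pairs with 500 mg averaged 0.626 for 20 mg and 0.629 for 100 mg. The 100 mg libraries were also less alike than pairs of a 100 mg with a 4 mg library (0.623) or a 20 mg library (0.580). Leaving out 500 mg replicate 1 lowered the difference to 0.0425 (exact p = 0.0793), replicate 2 to 0.0427 (0.0836) and replicate 3 to 0.0424 (0.0836). Without all 3 of them, a choice made after seeing the data, it was 0.0449 (exact p = 0.104), and with all 12 libraries but by the share of the shorter list's peaks it was 0.00546 (exact p = 0.296).

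**Figure D4:**
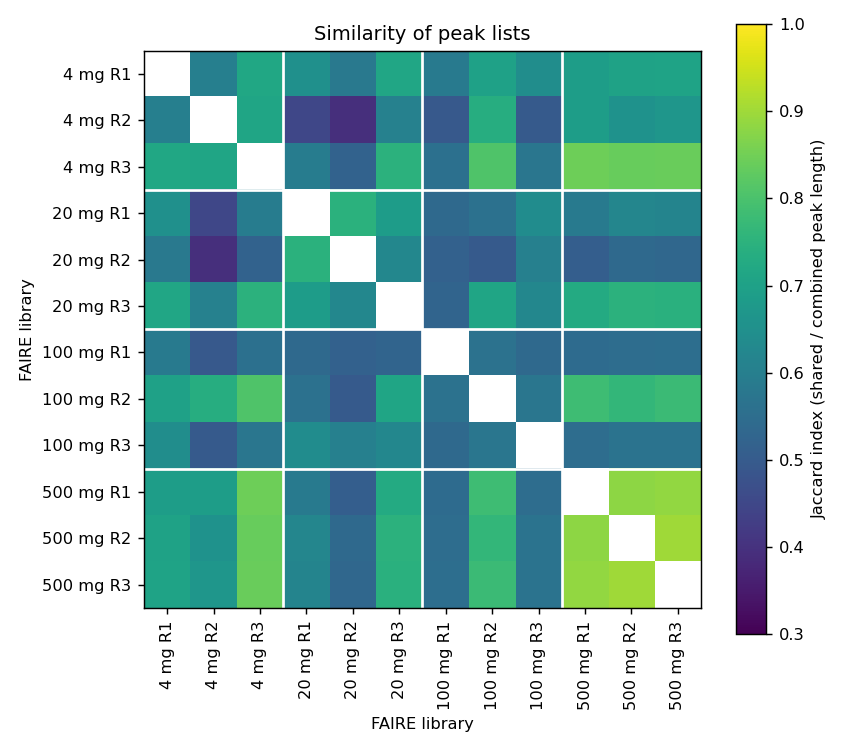
Jaccard index of peak length (colour scale) for each pair of the 12 FAIRE libraries (both axes), with white lines between biomasses. The 3 libraries at 500 mg form the brightest block, 0.881 to 0.899, and the 3 at 100 mg average 0.560.

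Promoters that separated a lower biomass from 500 mg, marked in 3 of 3 libraries of one and 0 of 3 of the other, were a small part of the 6000 genes. Between 4 mg and 500 mg there were 33 genes marked only at 4 mg and 19 marked only at 500 mg, and when an overlap of 50 bp or more counted as marking the balance turned to 23 and 37. Those with the highest fold enrichment at 4 mg were YIL060W, YFL002W-A, a Ty reading frame, one of a class over which peaks differed widely between libraries, YFL002W-B, which shares its window, RNR2, which encodes a ribonucleotide reductase subunit (chromosome X, 391904 to 392403), and ARE1, a sterol acyltransferase gene. Those at 500 mg were TIS11, whose product acts on mRNAs under iron shortage, MRPL37, of the mitochondrial ribosome, BIO3, of biotin synthesis (chromosome XIV, 733791 to 734290), and CAR2, ornithine transaminase, with its divergent neighbour DIF1. The windows of these named genes were overlapped by a peak in every library of both biomasses, and what differed was the position of the summit. A peak overlapped the window in every 500 mg library for 15 of the 33 genes and in every 4 mg library for 7 of the 19. Leaving out a library of the comparison loosens 3 of 3 to 2 of 2, so these totals can only stay or rise. The total of 52 became 94 without 4 mg replicate 1, 103 without 4 mg replicate 2, 149 without 4 mg replicate 3, 82 without 500 mg replicate 1 and 85 without 500 mg replicate 3.

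More promoters separated 20 mg from 500 mg, 123 marked only at 20 mg and 13 only at 500 mg, and 37 and 16 among the 3000 strongest peaks of each list. At 20 mg they were led by CBP1, needed for cytochrome b mRNA, CDC48, encoding an ATPase of protein degradation (chromosome IV, 238665 to 239164), QDR2, a multidrug transporter gene, and NDE2, a mitochondrial NADH dehydrogenase gene that shared its window with YDL085C-A. At 500 mg they were led by MOG1, of nuclear protein import, GCV3, of glycine cleavage, PRM8, SNF1, the AMP-activated kinase gene, and FCF2, of ribosomal RNA processing. Marking only at 1 biomass refers to the 2 compared: QDR2 was also marked in 3 of 3 libraries at 4 mg and at 100 mg, and CDC48 at 100 mg. A peak overlapped the window in every 500 mg library for 21 of the 123 genes and in every 20 mg library for 7 of the 13. The genes named at 20 mg were all among the 21. Of those named at 500 mg, MOG1, GCV3 and SNF1 were among the 7. The PRM8 window was overlapped in 1 library at 20 mg and the FCF2 window in 0. The total of 136 was 209 without 20 mg replicate 1 and 264 without 20 mg replicate 3.

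At 100 mg, 60 genes were marked only at 100 mg and 36 only at 500 mg, and the balance turned to 39 and 48 at a −log10 q of 5 or more and to 48 and 60 by overlap. Among the 3000 strongest peaks the counts were 39 and 13. TDA4, TNA1, encoding a nicotinic acid permease, CDC48, QDR2 and KGD2, the second subunit gene of 2-oxoglutarate dehydrogenase, led the first group, and BIO3, YAL065C, ORA1, PEX3, of peroxisome formation, and CDC123 the second. QDR2 and KGD2 were also marked in 3 of 3 libraries at 4 mg and at 20 mg, and CDC48 at 20 mg. A peak overlapped the window in every 500 mg library for 31 of the 60 genes and in every 100 mg library for 4 of the 36. The genes named at 100 mg were all among the 31. Of those named at 500 mg, BIO3, YAL065C and PEX3 were among the 4. The ORA1 window was overlapped in 2 libraries at 100 mg and the CDC123 window in 0. The total of 96 was 175 without 100 mg replicate 1 and 213 without 100 mg replicate 2. No p is given per gene, since 3 libraries against 3 separate a gene with an exact p of 0.1, the share that chance gives for values that do not overlap. The 3 comparisons share the 500 mg libraries, and overlaps between their genes were not tested.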

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

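Among the tests reported in this part, those of biomass as a source of the repeat coverage, of weaker detection for Ty frames and YRF1 genes apart, of read depth as a source of the peak numbers and of list length for 4 mg against 500 mg were chosen only after the result was seen.

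Peaks over repeats, ribosomal DNA and the mitochondrial chromosome differed widely between libraries. On the 43 repeat regions, Ty retrotransposon frames and subtelomeric YRF1 genes, peaks covered between 4.04% of the length in 20 mg replicate 2 and 89.7% in 4 mg replicate 2. The ribosomal DNA span annotated on chromosome XII (451786 to 466869) was covered to 100% in 8 libraries, 4 mg replicate 1 among them, to 89.1% in 100 mg replicate 3, to 42.2% in 20 mg replicate 1 and to 0% in 20 mg replicate 2 and 100 mg replicate 1. The mitochondrial chromosome held 3 peaks in 20 mg replicate 2 and 78 in 4 mg replicate 2. The 43 repeat genes were among the 6000 tested, and 2 of them, 1 and 3 were among the promoters separating 4 mg, 20 mg and 100 mg from 500 mg.

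Wide peaks over Ty reading frames covered 72.7% to 87.3% of their length in 7 libraries and 2.25% to 30.4% in the other 5, while the 8 YRF1 genes were touched in every library and covered for 93.3% to 100% in the 7 and 11.7% to 77.8% in the 5. Biomass as the whole source is argued against by the spread inside groups: over both kinds of repeat the libraries of 20 mg and of 100 mg spanned 86.9% and 78.9% of the range of all 12, and the exact permutation test over biomasses gave p = 0.186. Weaker detection was examined with regions outside repeats of matched summit enrichment at 500 mg. The 5 libraries covered these by 55.9 to 85.5 percentage points more than the Ty frames, with 59.9 points in the library ranking second lowest (51.7 over both kinds). For the YRF1 genes these values were 5.51 to 71.1 and 17.8, which leaves weaker detection open there. The regions were not matched in width and lay in peaks of all 500 mg libraries by construction. Even at 500 mg they exceeded the repeats of both kinds by 10.0 to 19.7 points. For the Ty frames the gap argues against a weakness common to all peaks of this summit enrichment. Weaker detection along wide frames cannot be judged from it and stays open. Complete removal of multiply mapping reads is argued against by peaks in 34.9% to 95.3% of the repeat regions of the same libraries, in the lowest of them 7 of 35 Ty frames and 8 of 8 YRF1 genes. A filter that spares reads at unique stretches inside repeats, a difference in repeat copy number between colonies and a difference in the input libraries may each be involved and stay open.

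Peaks were most numerous at 20 mg, and the promoter share was lower at 20 mg and 500 mg than at 4 mg and 100 mg. Higher depth of the FAIRE libraries at 20 mg than in 6 others is argued against by the recovered reads per bp. These were 0.250 in the 3 libraries at 20 mg with 6204 peaks or more and in the 6 with 4994 to 5804. The highest at 20 mg lay 0.0672% over the lowest of the 6. The 3 libraries of lower recovered depth, 0.236 to 0.239, were outside this test. They belonged to 4 mg and 100 mg and held the fewest peaks, 4180, 4578 and 4987, so a part played by depth there stays open. List length as the whole source of the higher promoter share at 4 mg is argued against by a difference from 500 mg of 1.94 points among the 3000 strongest peaks (29.2% ± 0.214 against 27.2% ± 0.208, SD, n = 3 each), although it was -9.13 among the 500 strongest. For the 4 biomasses together list length stays open: the exact test gave p = 0.352 in the equal lists, where 100 mg minus 500 mg was 3.53 points (2.83 over whole lists) while the SD at 100 mg was 5.16 (0.645 over whole lists), and 20 mg minus 500 mg went from -0.569 to 0.333. The depth of the input libraries, fragment length and an effect of biomass on the chromatin itself were not tested and stay open.

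Upstream noncoding sequence held 41.7% of the 500 strongest summits and 6.38% of the 500 weakest, of which 85.3% lay in coding sequence. False calls as the source of the weak coding peaks were tested only for random positions. False calls that recur between libraries would raise the coverage too and cannot be told apart. Random ones would leave the 500 weakest coding peaks of a 500 mg library covered at 4 mg like shifted positions. They were covered for 30% to 63.2%, against 20.5% to 26.0% of shifted positions, and the ratio over the 9 library pairs was 1.44 to 2.43. The lowest ratio, with 4 mg replicate 2, missed the bound of 1.5 set beforehand (2.04 is the lowest of the other 4 mg libraries). False calls may therefore make up a part of the weak coding peaks and stay open. The 20 mg libraries covered 80.6% to 88.8% of the same peaks, against 27.1% to 31.2% of shifted positions. The 100 mg libraries covered 31.8% to 61.6%, against 18.5% to 25.4%. No biological explanation was tested for this pattern.

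For the promoters separating a lower biomass from 500 mg, the real grouping gave 52 at 4 mg where the highest of the other 9 splits gave 20, 136 at 20 mg against 22, and 96 at 100 mg against 20. In each comparison 1 of the 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05.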

How the results depend on the processing

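The tests with the 500 strongest peaks, without peaks of 3 kb or wider and without the 20 mg or 500 mg libraries were chosen only after the results were seen. The 3 lists per biomass and a depth known only indirectly set the limits here, and the exact p of 3 lists against 3 says nothing about stability. Differences from 500 mg, whose exact p is never under 0.1, kept their direction in 137 of the 150 values that an alternative moved and reversed in 13, and 98 further values left out a library outside the comparison and could not change. For 4 mg minus the others 79 of 83 moved values kept direction and side of the threshold and 4 reversed. Of 551 gene list values that moved, 512 kept both, 15 newly passed, 23 no longer passed and 1 reversed. Except where an alternative's construction shows it, the cause was not tested.

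Percent of variance between biomasses, with each library left out, ran from 62.2 to 88.4 for the number of peaks, from 53.5 to 64.7 for total length, from 89.2 to 93.5 for the promoter share (exact p up to 0.00214), from 31.7 to 77.5 for marked promoters and from 64.1 to 77.4 for recovery, where no value exists without a 500 mg library. The similarity difference ran from 0.0424 to 0.114 and gene lists passing from 6 to 8. Separating promoters, whose count can only stay or rise when a library of the comparison is left out, ran from 68 to 149 at 4 mg, from 150 to 264 at 20 mg and from 114 to 213 at 100 mg, and leaving out a library outside the comparison left them at 52, 136 and 96 by construction. The number of peaks gave 3.83% without the 20 mg libraries (exact p = 0.875), and equal lists give it no value. Total length gave 62.8% at the stricter −log10 q (exact p = 0.0336) and 60.7% without mitochondrial and ribosomal DNA peaks (exact p = 0.0482).

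With the 3000 strongest peaks the promoter share gave 30.7% (exact p = 0.352), recovery 56.9% (exact p = 0.0849), similarity 0.0550 (exact p = 0.0684), separating promoters 53 at 20 mg and 52 at 100 mg, and 3 gene lists passed. The 500 strongest peaks gave 28.3% for the promoter share (exact p = 0.422). Similarity was 0.00546 by the shorter list's share (exact p = 0.296), where both means were near 1 (0.911 within and 0.905 between biomasses), and 0.0449 without the 500 mg libraries (exact p = 0.104). Windows of 250 bp gave 22, 42 and 35 separating promoters at 4, 20 and 100 mg and 1 gene list, windows of 1000 bp 86 at 4 mg and 273 at 20 mg. Marking by overlap gave 231 at 20 mg and 11 gene lists, and 1 gene per shared window gave 3 lists. Newly passing as marked more often were, by Fisher's exact test, the glycolysis and fermentation list in 3 alternatives and the cell wall list in 4. The amino acid synthesis list did so in 2 and the galactose and oxidative stress lists in 1 each. In the other direction, marked less often, the ribosome biogenesis list newly passed in 2 (4 of 62 in each). The PAU list (0 of 24) and the haploid list (0 of 16) also passed as marked less often, in 1 each.

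Replicate numbers carried no pairing in the labels. Same-numbered libraries did not deviate together (18 pairs, correlations across genes -0.0509 to 0.0546, 0 over 0.1), and 3 of 12 libraries correlated best with their own number. With the replicate number as a block the number of peaks gave 76.9% (exact p = 0.0608) and recovery 72.7% (exact p = 0.0642), no longer past 0.05, and it changed no other call among the tests over biomasses.

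Reversed values were as follows. With equal lists, total length at 4 mg minus the others was 33.0 kb and at 20 mg minus 500 mg -273.7 kb, the promoter share at 20 mg minus 500 mg 0.333 points, marked promoters at 4 mg minus the others 0.378 points and recovery there 1.93 points. At the stricter −log10 q, 20 mg minus 500 mg was -50.6 kb and 0.234 points of promoter share, and marked promoters at 100 mg minus 500 mg -0.394 points. Windows of 250 bp gave 0.451 points of promoter share for 20 mg minus 500 mg, and windows of 1000 bp -0.133 points of marked promoters for 4 mg minus 500 mg. Marking by overlap gave -1.68 and -0.789 points for 4 mg and 100 mg minus 500 mg. The 500 strongest peaks gave promoter share differences of -3.22 points for 4 mg minus the others, -9.13 for 4 mg and -10.0 for 100 mg minus 500 mg. Without 100 mg replicate 1 the peak number at 100 mg minus 500 mg was 325.8 (range over left-out libraries -486 to 325.8), and without 20 mg replicate 3 total length at 20 mg minus 500 mg was -32.9 kb (range -32.9 to 197.9 kb). The COS family turned to a log2 odds ratio of 2.64 when marking in at least 9 of 12 libraries sufficed (Fisher's exact test, adjusted p = 0.0152, over its 20 alternatives 0.0152 to 1).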

Other observations

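The tests of tRNA, snoRNA and protein-coding genes against shifted positions and between biomasses were chosen only after the results were seen.

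Nutrient and stress genes outside the groups that passed still included promoters marked in all 12 libraries. Among phosphate genes, 4 of 16 were marked throughout (Fisher's exact test, adjusted p = 0.140), with SPL2 at a median fold enrichment of 3.40 and PHO84, the high-affinity phosphate transporter gene, at 3.17, while PHO11 and PHO12, encoding acid phosphatases, were never marked. Hexose transporters had 4 of 16 (exact test, adjusted p = 0.140), with HXT2 at 3.37, HXT13 at 3.00 and HXT3 at 2.91. Iron genes had 3 of 23 (exact test, adjusted p = 0.640), ISU1, of iron-sulfur cluster assembly, at 3.44 and FIT2, a cell wall mannoprotein gene, at 3.26. Sulfur and methionine genes had 3 of 27 (exact test, adjusted p = 0.828), with STR3 at 3.55 and MUP1, the methionine permease gene, at 3.01, and amino acid synthesis genes 11 of 58 (exact test, adjusted p = 0.0901). Galactose genes had 2 of 7 (exact test, adjusted p = 0.277), GAL2 at 3.20 and GAL3 at 2.80, with GAL7 and GAL80 never marked. A peak overlapped the GAL80 window in every library. Oxidative stress genes had 4 of 24 (exact test, adjusted p = 0.460), with GSH1 at 3.23 and YAP1 at 3.22 after CTT1, and heat shock genes 3 of 27 (exact test, adjusted p = 0.828), MDJ1, KAR2 and BTN2.

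Cell cycle and cell wall genes followed. G1 to S genes had 6 of 29 (exact test, adjusted p = 0.140), with YOX1, a repressor gene, at 3.52 and CLB5, an S-phase cyclin gene, at 3.50, and cell wall genes 7 of 32 (exact test, adjusted p = 0.0903), with CWP1 at 3.37 and SCW4 at 3.33 after SPI1. Ribosome biogenesis genes had 1 of 62, UTP5 (exact test, p = 0.0280, adjusted p = 0.0903), and proteasome genes 1 of 34, RPT4 (exact test, adjusted p = 0.426). Meiosis and sporulation genes had 3 of 55 (exact test, adjusted p = 0.557), SMK1, SPS4 and NDT80. None was marked throughout among 7 a-specific genes (adjusted p = 1), 5 alpha-specific genes (adjusted p = 1), 16 haploid and pheromone genes (adjusted p = 0.570), 24 PAU genes (adjusted p = 0.294) and 12 COS genes (adjusted p = 0.773), by Fisher's exact test. When any peak overlapping the window by 50 bp counted, 1417 of 6000 genes were marked in all libraries.

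Peaks overlapped protein-coding genes about as often as shifted positions, 54.8% ± 6.20 (SD, n = 12 libraries) of 6002 genes against 51.8%, a ratio of 1.02 to 1.11 per library. The percent was 50.3 ± 4.00 at 4 mg, 63.1 ± 0.319 at 20 mg, 51.0 ± 6.27 at 100 mg and 54.7 ± 1.13 at 500 mg (SD, n = 3 each), with 73.2% of the variance between biomasses (exact permutation p = 0.0112, not adjusted). The values above required an overlap of 50 bp or more. With any overlap counted, a peak lay over the coding sequence of 2084 of the 6000 genes in all 12 libraries. Of these, 262 also had a marked promoter in all 12 and 954 in none. By the same count 1215 genes had neither a marked promoter nor a peak over the coding sequence in any library.

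Genes for tRNAs lay in peaks often and snoRNA genes rarely. Of 275 tRNA genes, 57.3% ± 9.20 (SD, n = 12 libraries) overlapped a peak, 70 in every library and 55 in none, against 18.9% at shifted positions. Position by chance is argued against by the ratio to shifted positions, between 2.198 and 4.63 in the 12 libraries, while depletion of the surrounding sequence, repeated copies and mappability stay open. The share of tRNA genes did not pass the exact permutation test between biomasses (p = 0.390). Of 76 snoRNA genes 6.25% ± 0.992 overlapped a peak, against 22.1% at shifted positions, with 70 in no library and 3 in all. Among single RNA genes, RPR1, of RNase P, and LSR1, the U2 RNA, lay in peaks in 12 libraries, SCR1, of the signal recognition particle, in 11 and SNR19, the U1 RNA, in 2. TLC1, NME1, SNR6, SNR7 and SNR14 lay in none.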
